A study of Mus musculus with 8 samples.

How the data were processed

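The deposited data were 1 table of gene-level counts from RNA sequencing of isolated mouse cardiomyocytes, with 54752 Ensembl gene IDs and 8 libraries in 4 groups of 2. Per the submitters' processing notes, the authors checked the reads with FastQC and MultiQC, aligned them to mm10 with HISAT2, made the counts with featureCounts and tested them with DESeq2. Versions, the strand setting and the gene annotation are not given in the sources used here. Per the labels' protocols, total RNA was turned into libraries with the SMART and Nextera XT kits. The deposited values are whole numbers and were used as raw counts. Groups were taken from the sample labels, and every column of the table belonged to a sample. Gene names came from GENCODE M21, which named 54723 of the IDs and left 29 without a name.

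What follows was computed from those counts. Genes were kept by edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15, which left 14665. Library sizes were scaled by the trimmed mean of M-values (TMM), with factors between 0.759 and 1.23. The CPM values use these factors, and principal components used log2 CPM with a prior count of 2. Differences were tested with edgeR's robust quasi-likelihood F-test on 1 fit of the 4 groups, with 4 residual degrees of freedom and a common coefficient of variation of 3.03%. KO over both ages was tested in an additive fit of age and KO. P-values were adjusted by Benjamini-Hochberg over all genes tested in a comparison, and a gene was called at an adjusted p under 0.05. The SE of a log2 fold change was derived from the F statistic.

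The comparisons, the main settings and most alternatives to them were fixed before the data were examined. The 33 gene lists cover heart muscle structure and metabolism, growth, stress responses, RNA handling and markers of other cell types. They were tested with limma's camera on log2 CPM at a preset inter-gene correlation of 0.01, for lists with at least 5 measured members, with adjustment over the lists of a comparison. Camera with an estimated correlation and limma's fry were run beside it. Genes are named by rule: the 10 with the largest rise and the 10 with the largest fall among called genes with a mean CPM of at least 10, and up to 4 called members of each list, or 2 members where no member was called. For a gene with 0 counts in a group, the fold is a lower bound from a floor of 3 counts over that group, and with 1 to 3 counts it is a ratio with a 95% counting interval. Correlations between effects that share control libraries were set beside 100 simulated data sets without effects of age or KO. Permutation tests between lists used 100000 resamples and lists matched on expression 10000 draws.

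The procedure was tried on simulated counts with the real means, library sizes and spread, in which 200 genes per comparison were changed by known folds. Over the 6 comparisons it recovered 36 to 58% of genes changed 1.25-fold, 62 to 74% of those changed 1.5-fold, 72 to 94% at 2-fold and 72 to 100% at 4-fold, and 3.05 to 8.07% of its calls were unchanged genes. A list shifted by 1.25-fold, 1 of the 30 tested, was found in all 6. Of the unshifted lists 1 was called in KO against control at 3w and 0 in the other comparisons. The simulated spread was that between the libraries of a group, and all other genes had the same mean in every group. These rates therefore do not give the share of false calls in the real comparisons, where many genes change and that spread may be technical. The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.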

Results

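The series asked how the arginine methyltransferase Carm1, an enzyme that methylates histones and other proteins, bears on the maturation of mouse heart muscle after birth. Messenger RNA was sequenced from cardiomyocytes that had been isolated on a Langendorff perfusion system from hearts of mice with floxed Carm1 alleles. The mice had received adeno-associated virus carrying Cre recombinase, which deletes the floxed part of the gene, or GFP as control. No group received Cre without floxed alleles, so an effect of Cre itself cannot be told apart from loss of Carm1. Per the labels the hearts were mosaic, so that infected and uninfected cardiomyocytes lay side by side, and no sorting step is described. The 8 libraries form 4 groups of 2: control at 1w, control at 3w, Carm1 KO at 1w and Carm1 KO at 3w. The labels do not state outright whether the 2 libraries of a group came from separate animals. They give them different injection days, postnatal day 1 and 2 at 1w and 3 and 4 at 3w, in KO and control alike. Taken as written, this would mean separate animals. The days also run on with replicate number and age, so their meaning is uncertain. The p-values measure only the spread between these libraries, which may be technical.

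Total gene counts per library were 20818285 and 31702513 in control at 1w, 53671626 and 37293627 in control at 3w, 36136575 and 30683549 in KO at 1w, and 30912152 and 31325805 in KO at 3w. Between 40.7 and 47.8% of each library's counts came from mitochondrially encoded genes. Within a group the libraries lay close together: the coefficient of variation beyond counting noise was 3.45% in control at 1w, 4.00% in control at 3w, 1.30% in KO at 1w and 2.33% in KO at 3w. Each of these pairs still differed by more than sampling noise, with a chi-square per gene of 1.45 to 6.95, so all 8 were kept as separate libraries. This excess does not tell separate animals from 2 preparations of the same RNA. Age separated the libraries along the principal component with 70.4% of the variance, where the 1w libraries lay between -67.0 and -52.6 and the 3w libraries between 41.5 and 78.6. The next component, with 13.1%, separated KO (19.3 to 32.5) from control (-31.8 to -19.2). Component 3, with 9.61%, set control at 1w and KO at 3w (-23.7 to -20.7) against control at 3w and KO at 1w (18.6 to 26.0). This is also the split by the Y-linked counts given next. Summed counts of the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were 1 and 0 in control at 1w and 3 and 2 in KO at 3w, against 6765 and 4814 in control at 3w and 5025 and 4282 in KO at 1w. Presence of Y-linked transcripts therefore differed between KO and control at both ages, in opposite directions. At 1w alone and at 3w alone, a KO effect cannot be told apart from a difference that follows these transcripts. KO effects at 1w or at 3w below are differences between these groups.

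**Figure D1:**
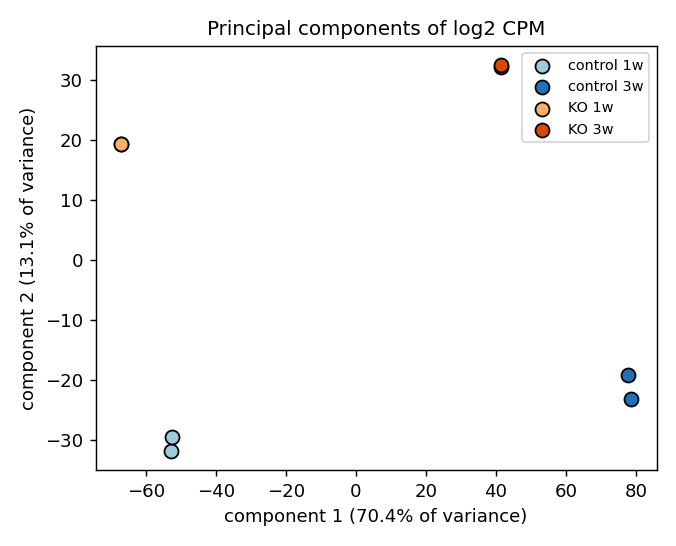
Principal components of log2 CPM over the 14665 genes tested, 1 point per library, coloured by group. Component 1 (x axis, 70.4% of variance) separates 1w from 3w and component 2 (y axis, 13.1%) separates KO from control, and the 2 libraries of each group lie close together.

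Carm1 itself (ENSMUSG00000032185, chromosome 9, 21546894 to 21592623, plus strand, GRCm38/mm10) stood at 40.5 and 39.1 CPM in the control libraries at 1w, 39.9 and 39.2 CPM in control at 3w, 22.2 and 22.4 CPM in KO at 1w and 17.3 and 17.9 CPM in KO at 3w. The log2 fold change of KO against control was -0.83 ± 0.055 (SE) at 1w (adjusted p = 3.4e-20) and -1.17 ± 0.060 at 3w (adjusted p = 1.1e-25, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with all 4 KO libraries below all 4 control libraries. The change at 3w less that at 1w was -0.34 ± 0.082 on the log2 scale (adjusted p = 0.00066, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The gene-level count includes reads from exons outside the deleted part and from uninfected cells. Below, levels are CPM as mean ± SD of the 2 libraries of a group, and changes are log2 fold changes ± SE from edgeR. Calls within a gene list were also adjusted over that list alone, and these counts are given where they differ from those over all genes.

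**Figure D2:**
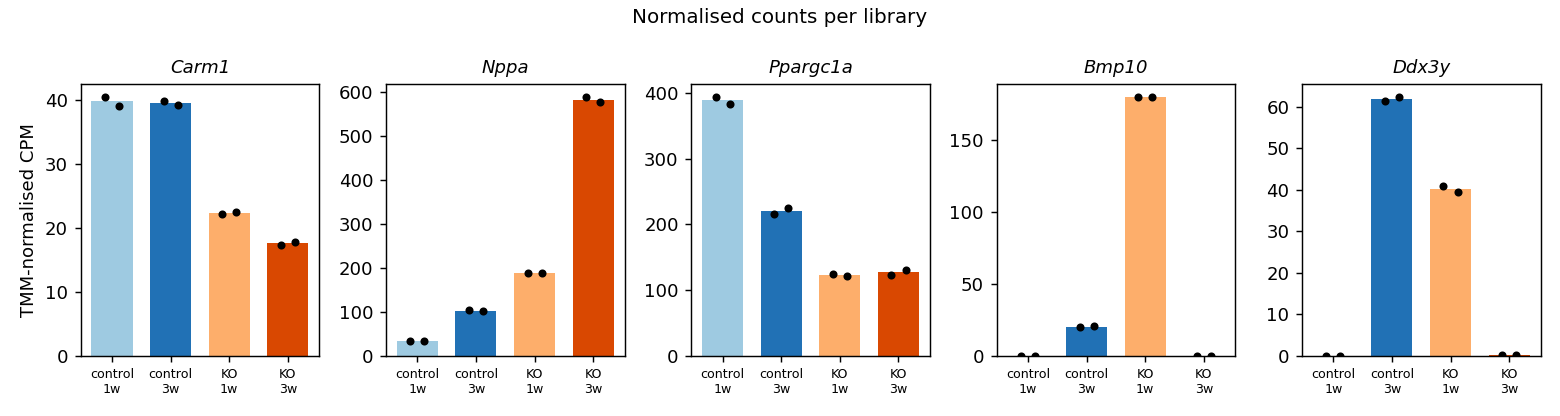
TMM-normalised CPM (y axis) of Carm1, Nppa, Ppargc1a, Bmp10 and Ddx3y in the 4 groups (x axis), with points for the 2 libraries of a group and bars for their mean. Carm1 lies between 39.1 and 40.5 CPM in the 4 control libraries and between 17.3 and 22.4 CPM in the 4 KO libraries, while the Y-linked gene Ddx3y is present in control at 3w and KO at 1w and near 0 in the other groups.

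At 1w, the KO hearts had lower levels of genes for burning fat. All 28 measured members of the fatty acid oxidation list fell (median log2 fold change -0.26; camera adjusted p = 1.5e-10). Among them Acadm, the medium-chain acyl-CoA dehydrogenase, fell from 687 ± 7.5 to 492 ± 2.6 CPM (-0.48 ± 0.029). Pdk4, a kinase that inhibits pyruvate dehydrogenase, fell from 1302 ± 8.5 to 894 ± 1.7 CPM (-0.54 ± 0.027), and Fabp3, the heart fatty acid binding protein, by 0.35 on the log2 scale. Ppargc1a, a coactivator of mitochondrial gene programmes, fell from 389 ± 8.3 to 123 ± 2.3 CPM (-1.66 ± 0.035). Of the tricarboxylic acid cycle genes 11 of 21 fell (camera adjusted p = 0.0018, adjusted p = 0.067 with an estimated correlation), among them the isocitrate dehydrogenase Idh2 (-0.69 ± 0.027). Nuclear encoded subunits of oxidative phosphorylation fell in 26 of 42 cases, by a median of only -0.14 (camera adjusted p = 3.8e-06, adjusted p = 0.098 with an estimated correlation). Of the mitochondrially encoded genes 7 of 13 fell (median -0.11; camera adjusted p = 0.014, adjusted p = 0.22 with an estimated correlation). In the glycolysis list 11 members rose and 5 fell of 22 (13 and 5 adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.066).

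Contractile and excitation genes moved the same way at 1w. In the mature sarcomere list 13 of 17 measured members fell and 1 rose (median -0.19; camera adjusted p = 0.00026, adjusted p = 0.067 with an estimated correlation), including the ventricular myosin light chain Myl2 (-0.38 ± 0.023) and the myosin binding protein Mybpc3 (-0.38 ± 0.025). Of 31 genes for calcium handling, T-tubules and ion channels 20 fell and 6 rose (22 and 6 adjusted over the list alone; median -0.22; camera adjusted p = 3.3e-05, adjusted p = 0.067 with an estimated correlation). The calcium binding protein Hrc of the sarcoplasmic reticulum fell from 347 ± 0.62 to 201 ± 0.082 CPM (-0.79 ± 0.030), the inward rectifier channel Kcnj2 by 1.07 and the gap junction gene Gja1 by 0.64 on the log2 scale. Among cardiac and metabolic transcription factors 18 of 36 fell and 7 rose (camera adjusted p = 0.00085, adjusted p = 0.11 with an estimated correlation), with Tbx20 at -0.70 and Gata6 at -0.71. In the fetal cardiac programme 10 of 19 members rose and 3 fell (camera adjusted p = 0.0013, adjusted p = 0.079 with an estimated correlation). That list includes Myl7, Myl4, Nppa and Hcn4, which are also on the atrial list. Nppa, which encodes atrial natriuretic peptide and is made in atria and in fetal or stressed ventricle, rose from 34.4 ± 0.024 to 189 ± 0.44 CPM (2.46 ± 0.038).

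Markers of several other cell types and of atrial muscle were also higher in KO at 1w, while erythroid markers fell in 4 of 6 cases (1 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.0030, adjusted p = 0.079 with an estimated correlation). All 22 measured extracellular matrix genes rose (median 0.87; camera adjusted p = 1.7e-14), and so did all 15 cardiac fibroblast markers (median 0.82; camera adjusted p = 4.3e-10). Col1a1 rose from 165 ± 11 to 359.8 ± 5.3 CPM (1.13 ± 0.035) and the matricellular gene Postn from 209.9 ± 6.7 to 392 ± 3.7 CPM (0.90 ± 0.034). Macrophage and myeloid markers rose in 16 of 18 cases, each at least 2-fold (median 1.66; camera adjusted p = 3.1e-11), for example the growth factor receptor Csf1r from 9.21 ± 0.57 to 27.9 ± 0.70 CPM (1.61 ± 0.073). Endothelial markers moved less, with 15 of 18 higher and 1 lower (17 and 1 adjusted over the list alone; median 0.25; camera adjusted p = 0.00029, adjusted p = 0.11 with an estimated correlation). Smooth muscle and pericyte markers rose in 7 of 12 cases and fell in 2 (camera adjusted p = 0.017, adjusted p = 0.099 with an estimated correlation). Epicardial markers rose in 7 of 10 (median 1.71; camera adjusted p = 0.00013, adjusted p = 0.067 with an estimated correlation), led by Upk3b (2.20 ± 0.12). Atrial and conduction genes rose in 10 of 14 cases (11 adjusted over the list alone; camera adjusted p = 3.4e-07, adjusted p = 0.079 with an estimated correlation). The atrial growth factor Bmp10 stood at 0.118 ± 0.012 CPM in control and 179.7 ± 0.28 CPM in KO at 1w. The atrial light chain Myl7 was at 7.92 ± 0.63 and 94.6 ± 2.4 CPM (3.56 ± 0.063), and Myl4 at 11.5 ± 0.65 and 114 ± 0.38 CPM (3.30 ± 0.056).

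Proliferation and stress genes formed a further group at 1w. The counts do not tell which cells expressed these genes, and markers of several other cell types were higher in the same KO libraries. Of 27 G2/M and mitosis genes 25 rose (median 0.44; camera adjusted p = 0.00044, adjusted p = 0.067 with an estimated correlation), among them the proliferation marker Mki67 from 55.9 ± 5.0 to 76.8 ± 0.17 CPM (0.47 ± 0.048). Among S-phase genes 10 of 24 rose and 1 fell (camera adjusted p = 0.034, adjusted p = 0.12 with an estimated correlation). Immediate early genes, which tissue dissociation also induces, rose in 16 of 23 cases and fell in 3 (median 0.88; camera adjusted p = 1.1e-05, adjusted p = 0.099 with an estimated correlation). Egr1 went from 33.4 ± 2.6 to 152 ± 0.056 CPM (2.17 ± 0.043) and Ccn2 from 34.6 ± 1.5 to 156 ± 0.95 CPM (2.18 ± 0.044). The nuclear receptors Nr4a1 (-1.15 ± 0.037) and Nr4a3 (-2.40 ± 0.068) fell. Integrated stress and unfolded protein response genes rose in 14 of 22 cases and fell in 2 (camera adjusted p = 0.00076, adjusted p = 0.067 with an estimated correlation), with the folate enzyme Mthfd2 at 1.54 ± 0.15. Of 28 interferon response genes 8 rose and 1 fell (camera adjusted p = 0.0067, adjusted p = 0.079 with an estimated correlation). Other large changes at 1w were the complement gene C3 (3.00 ± 0.077), Podn (2.68 ± 0.097) and the secreted Dkk3 (2.48 ± 0.083) upward. Lower in KO were Stbd1, which tethers glycogen to membranes (-4.10 ± 0.10), Tmem100 (-2.14 ± 0.075), Gcnt1 (-2.13 ± 0.077) and the kinase Sik1 (-1.59 ± 0.041). The Y-linked genes were higher in KO in the same libraries: Eif2s3y, with 0 counts in control, was at least 966-fold higher against a floor of 3 counts over the group. Ddx3y, with 1 count in control, had a ratio of 2431 (95% counting interval 436 to 96035).

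Over all 14665 genes tested, 6305 passed an adjusted p of 0.05 at 1w in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3373 higher and 2932 lower in KO, and 944 of them changed at least 2-fold (722 higher, 222 lower). Each gene named above as changed passed this test, with both KO libraries on the same side of both control libraries. The counting interval and the floor cover counting error only. DESeq2 called 4043 genes in place of 6305, and 4 of the 23 lists past the threshold stayed past it with an estimated correlation.

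At 3w, metabolic genes were again lower in KO, and matrix, fibroblast, smooth muscle and interferon response genes were higher. All 28 fatty acid oxidation genes fell again (median -0.48; camera adjusted p = 5.9e-13). Pdk4 fell from 2271 ± 96 to 679 ± 0.66 CPM (-1.74 ± 0.028), the uncoupling protein Ucp3 from 117 ± 6.3 to 49.9 ± 1.7 CPM (-1.23 ± 0.044) and Hadh, an enzyme of the oxidation spiral, by 0.74 on the log2 scale. Nuclear encoded oxidative phosphorylation genes fell in 41 of 42 cases (42 adjusted over the list alone; median -0.46; camera adjusted p = 6.1e-16), among them Ndufa5 (-0.82 ± 0.034) and Atp5b (-0.49 ± 0.024). Tricarboxylic acid cycle genes fell in 20 of 21 cases (median -0.44; camera adjusted p = 6.0e-10), with Idh2 at -0.71 ± 0.027 and Sdhb at -0.59 ± 0.031. Of 13 mitochondrially encoded genes 9 fell (median -0.37; camera adjusted p = 0.00031, adjusted p = 0.16 with an estimated correlation). Glycogen metabolism genes fell in 11 of 15 cases and rose in 1 (camera adjusted p = 0.00080, adjusted p = 0.050 with an estimated correlation), the exception being Stbd1, higher in KO at 1.86 ± 0.089. In the glycolysis list 11 fell and 4 rose of 22 (12 and 5 adjusted over the list alone). The insulin-responsive glucose transporter Slc2a4 fell from 517 ± 26 to 282 ± 2.0 CPM (-0.87 ± 0.033), and the list did not pass (camera adjusted p = 0.14). Its median of -0.09 and its mean of 0.07 differ in sign.

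Of the contractile genes at 3w, 13 of 17 mature sarcomere genes fell and 1 rose (median -0.28; camera adjusted p = 0.00020). The Z-disc cap gene Tcap fell from 1098 ± 32 to 465 ± 19 CPM (-1.24 ± 0.037) and the adult myosin Myh6 by 0.36 on the log2 scale. Calcium handling, T-tubule and channel genes fell in 19 of 31 cases and rose in 8 (19 and 9 adjusted over the list alone; median -0.23; camera adjusted p = 0.012, adjusted p = 0.16 with an estimated correlation). Among them Hrc fell from 1417 ± 51 to 605 ± 1.9 CPM (-1.23 ± 0.029), Kcnj2 by 1.33 and triadin, Trdn, by 0.71 on the log2 scale. In the fetal cardiac programme 11 of 19 rose and 6 fell (median 0.82; camera adjusted p = 0.048, adjusted p = 0.22 with an estimated correlation). Nppa rose from 102 ± 1.6 to 583 ± 9.5 CPM (2.51 ± 0.034), the related peptide Nppb from 74.7 ± 4.6 to 189 ± 2.6 CPM (1.33 ± 0.038) and Ankrd1, a stretch-responsive gene, from 169 ± 5.2 to 915 ± 14 CPM (2.44 ± 0.031). The transcription factor Tbx5 fell by 1.05 and Ppargc1a by 0.80 on the log2 scale. The list of cardiac and metabolic factors as a whole did not pass (13 lower and 12 higher of 36, 13 and 13 adjusted over the list alone; camera adjusted p = 0.34).

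Matrix and stromal markers were higher in KO at 3w as well. The matrix list had 21 of 22 members higher and 1 lower (median 1.00; camera adjusted p = 8.7e-13), with Postn at 1.86 ± 0.052 and Col15a1 at 1.84 ± 0.042. All 15 fibroblast markers rose (median 1.00; camera adjusted p = 4.9e-10), for example Col1a2 from 30.4 ± 1.9 to 85.4 ± 1.3 CPM. Smooth muscle and pericyte markers rose in 11 of 12 cases (12 adjusted over the list alone; median 1.12; camera adjusted p = 2.5e-08). Smooth muscle myosin Myh11 went from 2.67 ± 0.13 to 23.1 ± 0.31 CPM (3.12 ± 0.095) and the pericyte gene Rgs5 from 75.6 ± 1.9 to 167 ± 2.4 CPM (1.14 ± 0.037). Macrophage and myeloid markers rose in 16 of 18 cases and fell in 1 (median 0.67; camera adjusted p = 3.1e-06). Endothelial markers split 10 higher and 4 lower of 18 (camera adjusted p = 0.097), with Kdr at 0.85 ± 0.045 and Vwf at -0.56 ± 0.052. Epicardial markers fell in 7 of 10 cases and rose in 2 (camera adjusted p = 0.14), and atrial and conduction genes fell in 7 of 14 and rose in 6 (camera adjusted p = 0.44). Within the atrial list Bmp10 was at 20.3 ± 0.78 CPM in control and 0.0699 ± 0.049 CPM in KO, Myl7 at 13.6 ± 0.45 and 1.84 ± 0.19 CPM (-2.89 ± 0.12), and Myl4 at -1.76 ± 0.075 on the log2 scale.

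Among proliferation and defence genes at 3w, 15 of 27 G2/M genes rose (median 0.71; camera adjusted p = 0.00024), from low levels: Mki67 went from 2.81 ± 0.17 to 4.31 ± 0.56 CPM (0.63 ± 0.14). As at 1w, the counts do not tell which cells expressed these G2/M genes. S-phase genes did not pass as a list, with 7 higher and 4 lower of 24 (camera adjusted p = 0.34). Interferon response genes rose in 22 of 28 cases (median 0.78; camera adjusted p = 5.2e-07), with the class I gene H2-K1 at 0.53 ± 0.060 and the RNA sensor Ddx58 at 1.01 ± 0.12. The stress cytokine Gdf15 rose from 0.461 ± 0.15 to 9.39 ± 0.36 CPM. Herpud1, a gene of endoplasmic reticulum protein disposal, fell from 796 ± 14 to 289 ± 2.1 CPM (-1.46 ± 0.032). Their list had 13 members higher and 6 lower of 22 (camera adjusted p = 0.18). Immediate early genes rose in 13 of 23 cases and fell in 6 (camera adjusted p = 0.020, adjusted p = 0.34 with an estimated correlation). Further large changes at 3w were Psca (5.74 ± 0.16), the microtubule protein Map1a (3.36 ± 0.091) and tropomyosin Tpm2 (2.80 ± 0.094) upward. Lower were Gcnt1 (-3.15 ± 0.087), Ogdhl (-1.93 ± 0.041), Rhbdl3 (-1.98 ± 0.10) and Shld1 (-1.78 ± 0.077). Gapdh (2.53 ± 0.30), Tubb2a (2.17 ± 0.079) and Rps2 (-1.95 ± 0.061) also passed, but have close copies in the genome with which reads may be shared. The Y-linked Eif2s3y, with 0 counts in KO, was at least 1208-fold lower in KO against the floor of 3 counts over the group.

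At 3w 7212 of 14665 genes passed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3577 higher and 3635 lower, of which 1390 changed at least 2-fold (1113 higher, 277 lower). The highest adjusted p among the genes named at 3w was 0.0025, for Gapdh in that test, with both KO libraries above both control libraries. With an estimated correlation 10 of the 17 lists past the threshold stayed past it.

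**Figure D3:**
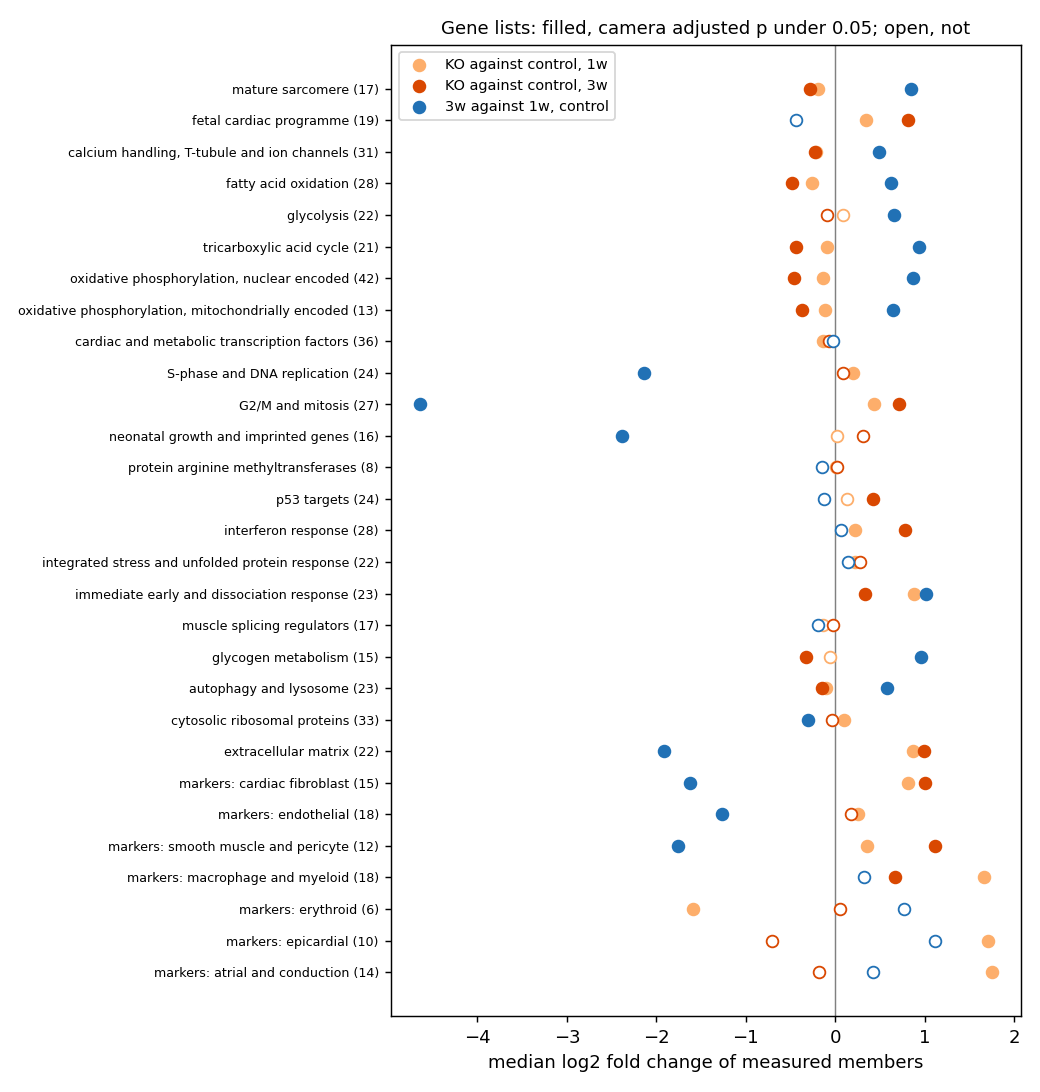
Median log2 fold change (x axis) of the measured members of each gene list (y axis, number measured in brackets) in KO against control at 1w and at 3w and in 3w against 1w in control, with filled points for camera adjusted p under 0.05 at the preset correlation and open points for the rest. Fatty acid oxidation, tricarboxylic acid cycle and oxidative phosphorylation lie left of 0 in KO and right of 0 with age, and extracellular matrix and fibroblast markers do the reverse.

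Taking both ages in 1 additive fit, the comparison of 4 KO with 4 control libraries gave the average KO effect over the ages, any effect of Cre included. Nppa rose by 2.48 ± 0.040 (adjusted p = 2.2e-09, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), higher in 4 of 4 KO libraries. At 1w the atrial genes Bmp10, Myl7 and Myl4 were higher in the same KO libraries. Whether atrial tissue adds to the 1w part of the Nppa rise stays open. Other genes higher at both ages, each also called at 1w and at 3w, were Podn (2.08 ± 0.20), the collagen Col6a3 (1.47 ± 0.11), Hmcn2 (1.43 ± 0.076), the secreted peroxidase Gpx3 (1.42 ± 0.062) and the stress-induced factor Atf3 (1.08 ± 0.047). Lower at both ages were Gcnt1 (-2.60 ± 0.20), Rasgef1b (-1.34 ± 0.063), Ppargc1a (-1.23 ± 0.17), Kcnj2 (-1.20 ± 0.061), Pdk4 (-1.14 ± 0.24), the reticulophagy receptor Retreg1 (-1.11 ± 0.041), the apoptosis gene Bcl2l11 (-1.05 ± 0.10) and Hrc (-1.01 ± 0.084). By list, 27 of 28 fatty acid oxidation genes (28 adjusted over the list alone), 33 of 42 nuclear encoded oxidative phosphorylation genes (39) and 14 of 21 tricarboxylic acid cycle genes (17) were lower. Higher were 21 of 22 matrix genes, 15 of 15 fibroblast markers and 16 of 18 macrophage markers, 20 of 28 interferon response genes (22 over the list alone) and 18 of 27 G2/M genes (23). The weakest camera adjusted p of these 8 lists at the preset correlation was 8.7e-07, for G2/M. With an estimated correlation adjusted p = 0.074 was the lowest over all lists, so that 0 of the 20 lists past the threshold stayed past it, against 24 by fry.

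In this additive fit 4506 genes passed, 2385 higher and 2121 lower, and 739 of them changed at least 2-fold. With a block on the injection day of the labels 2371 genes passed. When the 2 libraries of each group were summed to 1 sample, an alternative chosen after the data had been seen, 1 residual degree of freedom was left and the coefficient of variation rose to 19.8%. That degree of freedom is the difference in KO effect between the ages, which the Y-linked transcripts also follow. The spread in this summed fit is therefore that difference and not a spread between replicates. In that fit edgeR called 0 genes for KO, with 1973 at an unadjusted p under 0.05. DESeq2 called 234 (166 higher, 68 lower), limma-voom 1, and camera 22 lists at the preset correlation.

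Next, the KO effect at 3w was set against that at 1w gene by gene through the interaction term. Some genes had opposite KO effects at the ages, among them Tnni1, Stbd1 and Ankrd1. Tnni1, slow skeletal troponin I and the fetal isoform of the heart, went from 529.6 ± 17 CPM in control to 318 ± 3.7 CPM in KO at 1w. At 3w it went from 0.374 ± 0.18 to 3.91 ± 0.44 CPM, a difference of 4.02 ± 0.18. Stbd1 (5.95 ± 0.14), Ankrd1 (2.59 ± 0.042), Map1a (3.32 ± 0.12), the kinase Nuak1 (2.11 ± 0.077) and the scaffold Magi3 (2.11 ± 0.083) had KO effects that were more positive at 3w. Bmp10, Myl7 (-6.45 ± 0.13), Myl4 (-5.05 ± 0.093), sarcolipin, Sln (-8.44 ± 0.27), C3 (-3.50 ± 0.10), Dkk3 (-3.21 ± 0.16) and Tecrl, a gene linked to inherited arrhythmia (-2.86 ± 0.066), had effects that were more negative at 3w. The KO effect on Ppargc1a was smaller at 3w (0.86 ± 0.049), that on Pdk4 larger (-1.20 ± 0.039). Among nuclear encoded oxidative phosphorylation genes 35 of 42 had a lower effect at 3w (36 adjusted over the list alone; camera adjusted p = 6.5e-10, adjusted p = 0.097 with an estimated correlation). The same held for 20 of 28 fatty acid oxidation genes (23 over the list alone; camera adjusted p = 2.4e-05, adjusted p = 0.051 with an estimated correlation). Of the tricarboxylic acid cycle genes it held for 17 of 21 (camera adjusted p = 4.5e-06, adjusted p = 0.051 with an estimated correlation). Smooth muscle and pericyte markers had higher effects at 3w in 10 of 12 cases (camera adjusted p = 5.7e-07, adjusted p = 0.051 with an estimated correlation). Macrophage markers had lower ones in 15 of 18 (camera adjusted p = 3.5e-07, adjusted p = 0.051 with an estimated correlation).

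The interaction passed for 5215 genes, 2587 higher and 2628 lower, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; DESeq2 called 3351, and with an estimated correlation camera called 0 of the 16 lists past the preset threshold (fry 25). Presence of Y-linked transcripts follows the same contrast of the 4 groups as the interaction, so this design gives no fit that holds it fixed. Between the ages, 1582 genes were higher in KO in both (823 expected from independent lists) and 1447 lower in both (727 expected), while 915 were called in opposite directions (1551 expected). The 2 KO effects share no library. Across genes, which are not independent replicates, their log2 fold changes had a Pearson correlation of 0.14 and a Spearman correlation of 0.34. Among the genes with a mean CPM of at least 10 the Pearson value was -0.05 and the Spearman value 0.35, and over autosomal genes 0.23 and 0.35.

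Maturation itself, 3w against 1w in control hearts, showed lower growth genes and higher genes of energy supply. The fetal troponin Tnni1 fell from 529.6 ± 17 to 0.374 ± 0.18 CPM (-10.36 ± 0.076). All 27 G2/M genes fell at least 2-fold (median -4.64; camera adjusted p = 1.7e-11). Among them Mki67 fell from 55.9 ± 5.0 to 2.81 ± 0.17 CPM (-4.31 ± 0.084), Top2a (-4.80 ± 0.11), Ccna2 (-5.12 ± 0.14) and Anln (-5.41 ± 0.15). S-phase genes fell in 21 of 24 cases (median -2.14; camera adjusted p = 7.1e-08), and neonatal growth and imprinted genes in 14 of 16, with 1 higher (camera adjusted p = 0.00031), among them H19 (-3.89 ± 0.041). All 21 tricarboxylic acid cycle genes rose (median 0.94; camera adjusted p = 1.3e-08) and 41 of 42 nuclear encoded oxidative phosphorylation genes (42 over the list alone; median 0.88; camera adjusted p = 5.2e-13). Fatty acid oxidation genes rose in 25 of 28 cases, with 2 lower (median 0.63; camera adjusted p = 4.4e-07), and glycolysis genes in 16 of 22, with 4 lower (median 0.65; camera adjusted p = 0.00038, adjusted p = 0.088 with an estimated correlation). Lipoprotein lipase, Lpl, rose from 1464 ± 14 to 4927 ± 14 CPM (1.75 ± 0.025), citrate synthase, Cs, from 1081 ± 31 to 2497 ± 89.8 CPM (1.21 ± 0.027), Slc2a4 by 2.10 and hexokinase Hk2 by 1.68 on the log2 scale. Glycogen metabolism genes rose in 14 of 15 cases and fell in 1 (camera adjusted p = 7.8e-06).

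Contractile and calcium genes rose with age in control: 16 of 17 sarcomere genes, with 1 lower (median 0.85; camera adjusted p = 1.8e-06). So did 22 of 31 calcium, T-tubule and channel genes, with 7 lower (median 0.49; camera adjusted p = 0.0015, adjusted p = 0.10 with an estimated correlation). Titin, Ttn, rose from 2216 ± 74 to 5106 ± 53 CPM (1.20 ± 0.025), Myh6 by 1.34, the calcium pump Atp2a2 by 0.91 and Hrc by 2.03 on the log2 scale, whereas the channel subunit Kcne1 fell (-1.91 ± 0.037). Among transcription factors Tbx20 fell (-1.94 ± 0.035), while the thyroid hormone receptor Thrb (1.87 ± 0.075) and the retinoid receptor Rxrg (1.61 ± 0.057) rose. Matrix genes fell in 21 of 22 cases (median -1.92; camera adjusted p = 2.0e-10), with Postn going from 209.9 ± 6.7 to 11.9 ± 0.61 CPM (-4.13 ± 0.046). Markers of some other cell types fell alongside: 14 of 15 fibroblast markers with 1 higher (camera adjusted p = 8.2e-06) and all 12 smooth muscle and pericyte markers (camera adjusted p = 8.7e-06). So did 13 of 18 endothelial markers with 4 higher (camera adjusted p = 0.0059, adjusted p = 0.23 with an estimated correlation). Macrophage markers did not pass as a list (7 higher and 6 lower of 18, camera adjusted p = 0.39), nor did epicardial markers (6 higher and 4 lower of 10, camera adjusted p = 0.49). Erythroid markers rose in 5 of 6 cases without passing as a list (camera adjusted p = 0.071). Autophagy and lysosome genes rose in 18 of 23 cases and fell in 2 (camera adjusted p = 0.00010), and immediate early genes rose in 13 of 23 and fell in 5 (13 and 6 adjusted over the list alone; camera adjusted p = 0.029, adjusted p = 0.36 with an estimated correlation). Further genes of large change were the transcript-binding protein Csdc2 (5.04 ± 0.060), the channel Kcnj14 (6.01 ± 0.17), xanthine dehydrogenase, Xdh (5.09 ± 0.11), and the endoplasmic reticulum gene Herpud1 (3.64 ± 0.036) upward. Downward went the intermediate filament Nes (-4.21 ± 0.059), Thbs1 (-4.66 ± 0.090) and Marcksl1 (-5.02 ± 0.11). Carm1 itself had a difference of -0.00 between the ages in control (adjusted p = 0.95 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

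With age 10388 genes passed in control (5114 higher, 5274 lower; 3962 at least 2-fold) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The injection day in the labels and the presence of Y-linked transcripts both differ between the ages in control, so that neither can be told apart from age here. In KO the Y-linked transcripts differ between the ages in the opposite direction.

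In KO hearts most of the genes with a large change in control changed less with age. Of the 3962 genes that changed at least 2-fold in control, 3301 changed less in KO; the difference itself passed for 1750 of these, against 103 genes with a larger change in KO. Hrc rose by 1.59 on the log2 scale in KO, Lpl by 1.49, Slc2a4 by 1.33, Cs by 0.75 and Ttn by 0.99; Tnni1 changed by -6.34, Postn by -3.17 and Mki67 by -4.15. Median changes were 0.54 in KO for nuclear encoded oxidative phosphorylation (41 of 42 higher; camera adjusted p = 2.3e-11) and 0.60 for the tricarboxylic acid cycle (20 of 21; camera adjusted p = 3.6e-08). They were 0.38 for fatty acid oxidation (22 of 28, 3 lower; camera adjusted p = 5.7e-05) and -1.59 for the matrix list (22 of 22 lower; camera adjusted p = 1.1e-11). Sarcomere genes rose in all 17 cases (camera adjusted p = 3.6e-08). Calcium, T-tubule and channel genes rose in 26 of 31 cases and fell in 5, with a median of 0.66 against 0.49 in control (camera adjusted p = 4.9e-06 in KO). The difference between KO and control did not pass for that list (9 higher and 8 lower, 9 lower adjusted over the list alone; median -0.011, mean 0.092; camera adjusted p = 0.60). Ribosomal protein genes fell in 26 of 33 cases and rose in 1, with a median of -0.51 against -0.30 (27 lower adjusted over the list alone; camera adjusted p = 7.4e-06, adjusted p = 0.086 with an estimated correlation); for the difference 11 were lower and 2 higher (median -0.14; camera adjusted p = 0.018, adjusted p = 0.37 with an estimated correlation). Among markers of other cells macrophage markers fell in 13 of 18 cases in KO, with 1 higher (camera adjusted p = 0.0013, adjusted p = 0.072 with an estimated correlation), and epicardial markers in 8 of 10 (9 adjusted over the list alone; camera adjusted p = 0.00071, adjusted p = 0.069 with an estimated correlation). Atrial and conduction genes fell in 10 of 14, with 2 higher (camera adjusted p = 0.0037, adjusted p = 0.19 with an estimated correlation), and erythroid markers rose in 5 of 6 (camera adjusted p = 0.010, adjusted p = 0.087 with an estimated correlation). In control the atrial list had 7 higher and 6 lower (camera adjusted p = 0.42). The difference between KO and control passed for these 4 lists at the preset correlation and for 0 of them with an estimated one, where the lowest adjusted p was 0.051. Among single atrial genes Nppa rose in both (1.58 ± 0.039 in control, 1.63 ± 0.032 in KO), Myl7 fell in KO (-5.68 ± 0.084) and Myl4 rose in control (1.10 ± 0.068) but fell in KO (-3.95 ± 0.062). In KO 9955 genes passed (4874 higher, 5081 lower; 3277 at least 2-fold) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The slope of the change in KO on that in control was 0.58, with a Pearson correlation of 0.69 across genes. Genes picked for a large change in control are apt to change less elsewhere by selection alone, and the tested differences within them carry the same selection. The difference between KO and control in change with age is also the interaction. Presence of Y-linked transcripts follows that contrast, so the smaller change in KO cannot be told apart from it.

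The KO effects at 3w were also set against maturation, for genes that changed at least 2-fold with age in control. Of the 1411 genes at least 2-fold higher with age in control, 816 were lower and 153 higher in KO at 3w; of the 2551 at least 2-fold lower with age, 1392 were higher and 47 lower in KO. At 1w the split was 226 lower and 460 higher among the former and 344 lower and 902 higher among the latter. These genes were picked on the same control libraries that the KO effect is measured against, which tilts the split at 3w toward the opposite sign, and the counts have no value for the case of no effect. Across genes the KO effect at 3w and the change with age in control had a Pearson correlation of -0.56, a Spearman correlation of -0.57 and a covariance of -0.399. Both contrasts hold the control libraries at 3w. In 100 simulations without any effect of age or KO the Pearson value was -0.46 and the covariance -0.0197. With no change with age the simulated contrasts hold noise alone. Their Pearson values, here and at 1w, therefore do not show what real maturation without a KO effect would give. The simulated covariance gives what shared control noise adds at the simulated means and spread. At 1w, where the control libraries at 1w are shared, the Pearson correlation was 0.08 (simulated 0.56), the Spearman correlation, of opposite sign, -0.053, and the covariance 0.0515 (simulated 0.0228). With 2 control libraries per age the controls could not be divided into parts of 2. Part of the covariance at 3w beyond the simulated value may therefore come from the shared controls. Y-linked transcripts were higher with age in control and lower in KO at 3w. Genes that follow them would have opposite signs in these contrasts too, and the design cannot separate this from a KO effect.

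**Figure D4:**
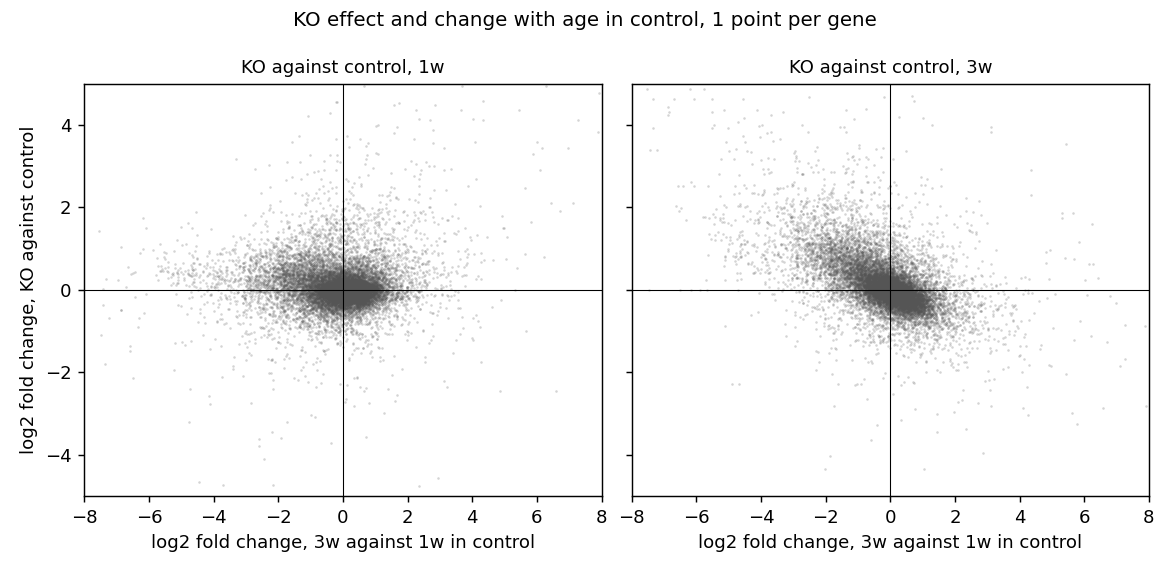
Log2 fold change of KO against control (y axis) at 1w and at 3w against log2 fold change of 3w against 1w in control (x axis), 1 point per gene; 58 of the 14665 genes lie outside the axes. At 3w the points run from upper left to lower right (Pearson correlation -0.56, simulated -0.46) and at 1w they do not (0.08, simulated 0.56). The simulations hold no effect of age or KO, so their values are not those of real maturation without a KO effect.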

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

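Results were picked out where the KO effect differed between the ages. The tests in this part were chosen after the result had been seen, apart from the regrouping of libraries, which was set earlier.

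KO effects that differ between the ages. The interaction passed for 5215 genes, and 915 genes were called in opposite directions at 1w and 3w. The pattern could follow the sex of the animals, since Y-linked counts take the same contrast of the groups, and the design cannot separate the 2. That 96.6% of the interaction calls lie outside the sex chromosomes does not help, since 14109 of all 14665 tested genes are autosomal. Atrial tissue in the KO libraries at 1w may also add to it, but the atrial list without Nppa (median difference -1.20) only restates the pattern, and Bmp10, 179.7 CPM there against 0.118 CPM in control, was also uneven at 3w (20.3 CPM in control, 0.0699 CPM in KO), so this stays open. At 3w the 4 atrial genes Bmp10, Myl7, Myl4 and Sln were lower in KO while Nppa was higher by 2.51. These 4 go against atrial tissue as the source of Nppa at 3w, but they were picked after the result had been seen. The whole atrial list, Nppa included, was split at 3w, with 7 lower and 6 higher of 14. Libraries from hearts of known sex with atria removed would separate these explanations.

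Stromal markers and fat oxidation. A lower share of cardiomyocytes could raise markers of all other cell types alike, but fibroblast markers exceeded endothelial markers by 0.56 at 1w and 0.82 at 3w in median log2 fold change (permutation p = 2e-05 each), which argues against that form of it. A change in which other cells were captured remains open. Dilution of cardiomyocyte RNA could lower fatty acid oxidation and sarcomere genes equally. At 3w fatty acid oxidation genes fell further than sarcomere genes by a median difference of -0.19 (permutation p = 0.0043). At 1w the difference was -0.069 (permutation p = 0.23). All these permutations shuffle genes between lists as if independent, which they are not. Their p-values do not measure a spread between hearts, so dilution is not excluded at either age.

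Many called genes with 2 libraries per group. The libraries of a group may come from the same animals or RNA: the highest coefficient of variation within a pair was 4.00%, and 4 of 4 pairs were alike in Y-linked counts. Taken as written, the labels go the other way, since they give the libraries of each group different injection days. Over the 34 ways to split the libraries with age kept in the model, 1, the real one, gave as many as 4506 calls, and the highest other gave 346. That other split follows the Y-linked counts, and only these 2 splits keep all 4 pairs whole, so the comparison tells little about chance between animals.

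Single genes with a difference between the ages were Stbd1 (5.95), Tnni1 (4.02), Map1a (3.32), Gapdh (2.62), Ankrd1 (2.59), the fibrillin Fbn2 (2.52), Plekhh1 (2.42), Nr4a3 (2.40), Magi3 (2.11) and Nuak1 (2.11), all as KO effect at 3w less that at 1w on the log2 scale. In the other direction lay Bmp10 (-18.65), Myl7 (-6.45), Myl4 (-5.05), C3 (-3.50), Kcnj14 (-3.36), Dkk3 (-3.21), Ush1c (-3.14) and Tecrl (-2.86). The fitted value for Bmp10 is not exact, since its levels in control at 1w and in KO at 3w were very low. The Y-linked Eif2s3y had -20.15 or beyond as a bound from the floor. The fitted value for Ddx3y, -20.36, is not exact, since it rests on 1 count in control at 1w, where the ratio of KO to control was 2431 (95% counting interval 436 to 96035).

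Of the lists, median differences were -0.21 for fatty acid oxidation, -0.22 for glycolysis, -0.27 for the tricarboxylic acid cycle, -0.30 for nuclear and -0.17 for mitochondrially encoded oxidative phosphorylation, and -0.14 for ribosomal proteins. The glycogen list had a median of -0.24 and a mean of 0.08. Cardiac and metabolic transcription factors had 0.18, interferon response genes 0.27, matrix genes 0.24, fibroblast markers 0.30, smooth muscle and pericyte markers 1.06 and erythroid markers 1.64. Macrophage markers had -0.94, epicardial markers -2.49 and the atrial list -0.92. Camera called all 16 at the preset correlation and 0 with an estimated one, against 25 lists by fry. Of the 34 genes named for the largest KO effects, 33 had a called difference between the ages, against 5215 of all 14665 tested genes; genes named for a large effect at 1 age are apt to differ by selection.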

How the results depend on the processing

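The 2-fold threshold, the summed library pairs and the autosomal comparison were chosen after the data had been seen.

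DESeq2 called 4043 genes at 1w in place of 6305, and 3351 for the difference between the ages in place of 5215. With a fold of at least 2 as well, 944 genes were left at 1w, 1390 of 7212 at 3w, 739 over both ages and 1123 for the difference. For change with age 3962 of 10388 were left in control and 3277 of 9955 in KO. The replicate numbers do not pair libraries (correlations of -0.022 to 0.008 between groups). A block on them gave 6172 calls at 1w, 7106 at 3w and 3670 over both ages, where a block on the injection day of the labels gave 2371 in place of 4506. Over both ages, summing the library pairs left edgeR with 0 calls and 1973 genes at an unadjusted p under 0.05, DESeq2 with 234 and limma-voom with 1. Without 1 library in turn the calls ranged from 4844 to 5360 at 1w, 6002 to 6561 at 3w, 3484 to 3863 over both ages and 4358 to 4891 for the difference. For change with age the ranges were 9363 to 9924 in control and 8967 to 9152 in KO.

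With an estimated correlation camera called 4 of 23 lists at 1w, 10 of 17 at 3w, 12 of 23 for age in KO, 0 of 16 for the difference and 0 of 20 over both ages. Fry called 30 lists for age in control in place of 18 and 25 for the difference.

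For the genes given next the sign of the value turned, and for the lists the direction of the camera or fry test, in some with a printed median of unchanged sign. None of them was called in the edgeR or camera test of the report. Fry leaves the medians as they were. Carm1 with age in control was -0.00 and became 0.010 with DESeq2 size factors, 0.00091 without the low-count filter, 0.0085 in DESeq2, 0.017 with thinned counts and 0.015 with only those groups, and ranged from -0.033 to 0.028 without 1 library. List medians without 1 library ranged from -0.024 to 0.066 for neonatal growth genes at 1w (fry 0.019), -0.051 to 0.022 for arginine methyltransferases at 3w and -0.10 to 0.36 for erythroid markers at 3w. With age in control they ranged from -0.021 to 0.13 for interferon genes (0.069 with the replicate block), while fry turned the direction of the p53 targets at a median of -0.13 (fry adjusted p = 0.00095). For the difference between the ages they ranged from -0.17 to 0.050 for S-phase genes and -0.066 to 0.072 for splicing regulators. Fry gave the other direction there at medians of 0.16 for the fetal programme (fry adjusted p = 0.0053), -0.067 for S-phase genes and 0.012 for splicing regulators.

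Over both ages Eif2s3y was 3.61 in DESeq2, 4.06 with summed pairs in DESeq2 and -3.59 to 3.22 without 1 library, and Ddx3y was 0.98, 0.80 and -3.46 to 2.94. Cidea ranged from -0.042 to 0.14, glycolysis from -0.020 to 0.0011 and ribosomal proteins from 0.0018 to 0.038. Summed pairs gave 0.054 for arginine methyltransferases and 0.031 for ribosomal proteins. The correlation of the KO effects moved from 0.14 to -0.049 at a mean CPM of at least 10 and to 0.23 over autosomal genes. The Pearson correlation of the KO effect at 1w with maturation moved from 0.08 to 0.13 at that level, where the Spearman values were -0.053 and -0.024. Correlations have no replicate spread, so a change of 1.5 times was taken as a shift.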

Other observations

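Red cell and lymphocyte transcripts moved between the groups. The globin Hbb-bs went from 45.4 ± 4.5 to 22.4 ± 0.83 CPM at 1w (-1.03 ± 0.070) and from 91.0 ± 7.7 to 127 ± 1.7 CPM at 3w (0.47 ± 0.055), and erythroid markers fell in 4 of 6 cases at 1w (1 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.0030, adjusted p = 0.079 with an estimated correlation). Globin genes have close copies, so reads may be shared among them. T cell receptor chain Trbc2 stood at 0.104 ± 0.031 CPM in control and 2.45 ± 0.58 CPM in KO at 1w, and Cd3g, with 3 counts in control, had a ratio of 13.7 (95% counting interval 4.45 to 68.4). The lymphocyte list rose in 6 of 9 cases at 1w and did not pass as a whole (camera adjusted p = 0.073). The immunoglobulin gene Ighm rose at 3w from 2.41 ± 0.84 to 10.4 ± 0.044 CPM (2.17 ± 0.14). The Schwann cell factor Sox10, with 1 count in control at 1w, had a ratio of 16.9 (95% counting interval 2.74 to 695.5), and Kcna1, with 0 counts, was at least 5.38-fold higher. Cidea, the 1 measured adipocyte marker, changed by -0.17 ± 0.058 at 1w and 0.31 ± 0.060 at 3w.

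Protein turnover, p53 and splicing genes changed in part. The ubiquitin ligases of muscle wasting fell in KO at both ages, Fbxo32 by 0.82 and 0.59 and Trim63 by 0.42 and 0.81 on the log2 scale. Their autophagy and lysosome list fell in 10 of 23 cases at 1w, with 3 higher (camera adjusted p = 0.026, adjusted p = 0.099 with an estimated correlation), and in 13 at 3w, with 5 higher (14 and 5 adjusted over the list alone; camera adjusted p = 0.030, adjusted p = 0.14 with an estimated correlation). Among p53 targets the cell cycle gene Btg2 rose at 1w (1.26 ± 0.049) and Phlda3 at 3w (2.13 ± 0.12), while the stress sensor Sesn1 fell at 3w (-0.97 ± 0.035). The p53 list passed at 3w (12 higher and 6 lower of 24, 13 and 6 adjusted over the list alone; camera adjusted p = 0.048, adjusted p = 0.16 with an estimated correlation). At 1w it had 9 higher and 4 lower (10 and 5; camera adjusted p = 0.32), and the difference between the ages did not pass (camera adjusted p = 0.35). The splicing regulators Qk (-0.51 ± 0.031) and Rbm24 (-0.44 ± 0.033) fell at 1w and Rbfox1 (-0.90 ± 0.057) at 3w, while their list did not pass at either age (camera adjusted p = 0.086 and camera adjusted p = 0.26). Of the other arginine methyltransferases Prmt5 rose at 1w (0.24 ± 0.056) and Prmt2 fell at 1w (-0.28 ± 0.079) and rose at 3w (0.60 ± 0.090), and the list passed at neither age (camera adjusted p = 0.80 and camera adjusted p = 0.93). Ribosomal protein genes, which have many pseudogenes, rose in 15 of 33 cases at 1w and fell in 2 (16 and 3 adjusted over the list alone; camera adjusted p = 0.050, adjusted p = 0.32 with an estimated correlation). Growth and imprinted genes included Grb10, lower at both ages (-0.45 ± 0.034 and -0.36 ± 0.036), and Meg3, higher at both (0.52 ± 0.066 and 0.76 ± 0.13). Xist had 0 counts in all 8 libraries, which neither shows nor excludes female animals because it lies within the antisense gene Tsix and the strand setting is not given in the sources used here.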
